A study of Mus musculus with 8 samples.

How the data were processed

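The series measured total RNA from 8 whole mammary tumors of MMTV-PyMT mice, a model in which the polyoma middle T antigen is driven in the mammary epithelium, on Affymetrix mouse gene arrays. Per the labels, the 8 are biological replicates, of which 4 came from conditional knockout mice that carried an MMTV-Cre transgene and floxed Mmp14 alleles (cKO), and 4 from littermates with the floxed alleles and no Cre transgene, which the submitters call wild type (WT). The mice were on a congenic FVB/NJ background and 3 to 4 months old, and tumors were taken from inguinal and thoracic glands. Biotinylated cDNA was made from 400 ng of RNA with the GeneChip WT Plus kit, per the labels' protocols.

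The deposited values are log2 signals, 1 per array row and tumor. The submitters' processing notes name RMA, which corrects background, normalizes between arrays and summarises probes on the log2 scale, and limma; versions and parameters are not given in the sources used here. The log2 scale was checked on the values, which lay between 0.853 and 12.9. The medians of the 8 arrays lay between 3.64 and 3.71, and their upper quartiles between 5.97 and 6.02. Any 2 arrays correlated across rows with r between 0.976 and 0.989, and shared identical values in at most 0.058% of rows, so each tumor counted as 1 replicate. No detection call or background signal was used here. A fold change of a dim row, on this scale, can understate the change in RNA, and the number of arrays limits the precision.

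Of 41345 rows, 23521 had 1 gene symbol in the platform annotation and stood for 22180 genes, 1814 had several symbols and 16010 are unnamed here. The symbols of 23328 rows were taken by gene identifier from the RefSeq gene table of mouse assembly GRCm38.p6, whether or not they differed from the platform's. The others kept the platform's name. That table served only for names and for which genes neighbour each other. Where a gene had several rows, the row with the highest mean over the 8 arrays stood for it in gene lists and in the values of list members. The genes named by direction were picked from all tested rows. Those that filled a direction were shown by the row with the smallest p among their rows that met the rule.

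Groups, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be chosen later. All 23521 rows with 1 symbol were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, cKO minus WT, no covariate). P-values were adjusted by Benjamini-Hochberg over all tested rows, with a threshold of adjusted p 0.05. The prior added 3.07 degrees of freedom to the residual 6. Mmp14 was also tested by an exact two-sided permutation of the 8 tumors, for which 4 against 4 allows no p below 0.0286.

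Gene lists for 45 pathways and cell types were fixed, and the 44 with at least 5 measured members were tested with fry from limma, adjusted over the 44 lists. The erythroid list had 1 of 8 members measured and was not tested. Fry asks whether the members of a list move, on balance, one way, and compares no list with other genes. Camera with a preset correlation of 0.01, camera with an estimated correlation and the mixed fry test were alternatives. A list score is the mean over members of a tumor's log2 signal minus that member's mean over the 8 tumors. Members past the threshold were counted over all genes and adjusted over the list alone.

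The named genes are Mmp14, up to 15 rows per direction with the largest log2 fold change among those past the threshold, and up to 4 members per list with the smallest p. The rows picked by direction had no overlap between the groups and a mean of at least 5 in the higher group. Where fewer than 15 passed, each direction was filled to 8 with the smallest p, given as values that did not pass. Predicted loci, small RNAs and olfactory or vomeronasal receptors were counted and not named.

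Both tests were tested on simulated data. In 10 simulated sets of the cKO and WT comparison over 23521 rows, with 50 rows changed at each size, the gene test recovered 28.6% of changes of 0.5 on the log2 scale, 87.0% of changes of 1, 99.8% of changes of 2 and 99.6% of changes of 3. Of all calls, 6.08% were false. The rows were drawn independently from normal distributions with each row's moderated variance, and 200 rows were changed per set. The data gave 2 calls, so the adjustment there required a smaller p than in the simulated sets. The shares recovered therefore do not carry over to the real comparison. In 200 simulated lists of 28 genes, fry passed 5% with no change and 88.5% with a shift of 0.8, both at an unadjusted threshold. The noise in these lists was set to fixed values and not taken from the data. The shift was larger than the mean difference of either list that passed below, so these shares do not carry over either.

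Alternatives were another quantile normalization, a shift of each array to 1 median, a filter on dim rows, another variance prior, array weights, the replicate number as a block, the array number (1 to 4 against 5 to 8) as a block, leaving out each tumor, other rows, thresholds and tests. The array numbers come from the labels, which do not say whether they mark a batch; each run of 4 held 2 tumors of each group. A fibroblast marker score as a covariate and adjustments over brighter rows only and without the row of Mmp14 were added after the data were seen. Which part of Mmp14 is floxed, and where on the gene the array's probes lie, is not given in the sources used here.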

Results

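Gene expression was measured in 8 whole MMTV-PyMT mammary tumors, 4 from mice in which a mammary Cre transgene targeted floxed Mmp14 (cKO) and 4 from floxed littermates without Cre (WT). Mmp14 encodes a membrane-anchored matrix metalloproteinase that cleaves collagen and activates other proteases, and the series title gives the aim as an array profile of tumors in which the gene was targeted in the carcinoma cells. Each tumor contributed 1 array of log2 signals, with array medians between 3.64 and 3.71. The first 3 principal components over the 8 tumors, from the 10186 rows with a mean of at least 5, took 36.4%, 20.1% and 16.8% of the variance. On none of the 3 did the groups separate. On the first, WT tumors ran from −26.6 to 3.0 and cKO tumors from −15.1 to 27.7. The groups differ both in the Cre transgene and in the targeted gene, and the samples were whole tumors that also hold cells outside the carcinoma.

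The first question was whether the targeted transcript was lower in the tumors labelled cKO. Mmp14 (row 17300279) fell in cKO tumors, from a mean log2 signal of 9.12 ± 0.19 (SD, n = 4) in WT to 7.72 ± 0.22 (SD, n = 4). The difference was −1.40 (SE 0.13), so that cKO tumors held 38.0% of the WT signal (95% confidence interval 30.8% to 46.9%), and limma gave an adjusted p of 0.0444. All 4 cKO tumors, between 7.44 and 7.98, lay below all 4 WT tumors, between 8.86 and 9.31, and the exact permutation p was 0.0286, the smallest that 4 against 4 allows. The cKO tumors thus kept a signal well above the array median. The difference was −1.13 within arrays 1 to 4 and −1.66 within arrays 5 to 8, with 2 tumors per group in each. With that array number as a block, limma's adjusted p was 0.0708, and leaving out single tumors gave differences from −1.48 to −1.30 and adjusted p from 0.0429 to 0.211, under the threshold only without cKO 1 or cKO 3. Because the position of the probes relative to the floxed part is not given in the sources used here, the remaining signal does not measure how much of the gene was deleted.

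The comparison of all genes asked which transcripts differed between cKO and WT tumors. Besides Mmp14, 1 gene passed the threshold among the 23521 rows tested. The agouti gene a (row 17378287), which encodes a secreted antagonist of the melanocortin receptor known from hair pigmentation, rose in cKO tumors from 3.68 ± 0.34 to 6.71 ± 0.66 (SD, n = 4 per group). That is a log2 difference in signal of 3.04 (SE 0.31), with an adjusted p of 0.0444 from limma, and it was seen in 4 of 4 cKO tumors. The WT signal of this gene lay at about the array median and was not shown to be above background, so the difference is one of signals and no fold of RNA is given. The difference was 2.87 within arrays 1 to 4 and 3.2 within arrays 5 to 8. The call of this gene rested on the adjustment counting Mmp14, the targeted gene, among the rows, and without that row limma's adjusted p of a was 0.0889 and no gene passed, with 2276 rows at an unadjusted p below 0.05.

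**Figure D1:**
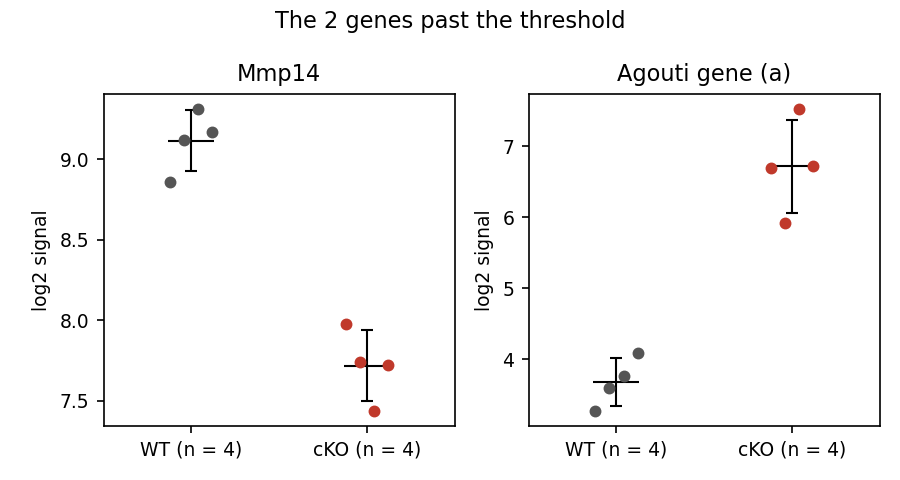
Log2 signal of Mmp14 (left) and of the agouti gene a (right) in each tumor, with WT in grey and cKO in red, the mean as a horizontal line and the SD as error bars (n = 4 per group). The signal of Mmp14 is lower in all 4 cKO tumors than in all 4 WT tumors, with group means of 9.12 and 7.72, and that of a is higher, with means of 3.68 and 6.71; the vertical axes do not start at 0.

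At an unadjusted p below 0.05, limma found 2277 rows, 1304 higher and 973 lower in cKO. The values of 1274 rows, or 5.42%, did not overlap between the groups, where chance gives 2.86% on average over divisions of the tumors. Rows that move together widen the spread around that average, and the excess was not tested. At an adjusted p of 0.10 there were 7 rows. The next genes higher in cKO by p, none of which passed, included several of chromatin, replication and cell division. The histone gene H2bc12 was higher by 1.00 (SE 0.12, adjusted p 0.0776), and the centromere gene Cenpi by 0.81 (SE 0.10, adjusted p 0.0776). Mcm5, a part of the helicase that opens DNA for replication, was higher by 0.80 (SE 0.10, adjusted p 0.0795). Cdc7, the kinase that starts replication at its origins, was higher by 0.72, and Cdca5, which holds sister chromatids together, by 0.64, both with an adjusted p of 0.142. Ulbp1, a ligand of the natural killer cell receptor NKG2D, was higher by 1.09 (adjusted p 0.0776), and Parvg, of the parvin family of adhesion proteins, by 0.54 (adjusted p 0.138). Among the genes lower in cKO, all with an adjusted p of 0.142, were Scnn1a, a subunit of the epithelial sodium channel, at −2.41 (SE 0.38), and Itgbl1 at −1.52 (SE 0.27). The actin-severing protein Scin stood at −1.13, the phosphatase Inpp5k at −0.69, Garre1 and Ttc7 both at −0.53, and the dynein light chain Dnal1 at −0.49.

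The gene-level count changed with 1 tumor left out, while the differences of both genes moved little. No gene passed in limma's fit without any 1 of the WT tumors or without cKO 4. In these 5 fits Mmp14 differed by −1.48 to −1.33 and the agouti gene by 2.90 to 3.17, and between 1597 and 2659 rows had an unadjusted p below 0.05. Without cKO 1 the genes were Mmp14 and Ulbp1, without cKO 2 the agouti gene alone, and without cKO 3 Mmp14, a and Cenpi.

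Gene lists fixed before the data were examined were then compared, and 2 of the 44 passed. The cell cycle list rose in cKO tumors. All 28 measured members were higher, by a mean of 0.70 and a median of 0.74 on the log2 scale, and the list score was −0.35 ± 0.14 in WT and 0.35 ± 0.17 in cKO (SD, n = 4 per group, exact permutation p = 0.0286). None of the 28 passed over all genes and 27 rose when adjusted over the list alone. Mcm5 rose by 0.80, the cyclin Ccne1, which acts at entry into DNA synthesis, by 0.79, and the mitotic kinase Plk1 by 0.70. The mitotic motor Kif11 rose by 0.86, and the member that did not pass, named after its values were seen, was Birc5 at 0.60. Limma's fry gave an adjusted p of 0.0321, and camera an adjusted p of 0.198 with an estimated correlation. The difference of the scores was 0.64 within arrays 1 to 4 and 0.76 within arrays 5 to 8, and with that block fry's adjusted p was 0.0511. With 1 tumor left out the mean lay between 0.62 and 0.75 and the adjusted p between 0.0312 and 0.0948, under the threshold only without WT 3 or cKO 4. Beside this list, the macrophage markers had a mean difference of 0.21, the fibroblast markers one of −0.60 and the luminal epithelial markers one of −0.23, none past the threshold. The macrophage score, too, was highest in cKO 4.

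The Notch pathway list fell in cKO tumors. Of 16 measured members 13 were lower, with a mean of −0.29 and a median of −0.23, and the list score was 0.15 ± 0.08 in WT and −0.15 ± 0.10 in cKO (SD, n = 4 per group, exact permutation p = 0.0286). No member passed over all genes, and 3 fell when adjusted over the list alone. These were the transcriptional repressor Hey2 (−1.36, SE 0.37), the endothelial receptor Notch4 (−0.38, SE 0.11) and Notch3 (−0.48, SE 0.14), a receptor of mural cells that was also among the pericyte markers. The Notch target Heyl stood at −0.25 and did not pass. Limma's fry gave an adjusted p of 0.0375, and camera an adjusted p of 0.145 with an estimated correlation. The score differed by −0.28 within arrays 1 to 4 and by −0.31 within arrays 5 to 8, with a fry adjusted p of 0.0511 under that block. After either rescaling of the arrays the mean was −0.28, close to that above, while the adjusted p was above the threshold (0.0803 and 0.122). With 1 tumor left out the mean lay between −0.34 and −0.26 and the adjusted p between 0.0415 and 0.146, under the threshold only without WT 3. Markers of pericytes had a mean difference of −0.33 and those of endothelium one of −0.24, neither past the threshold.

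**Figure D2:**
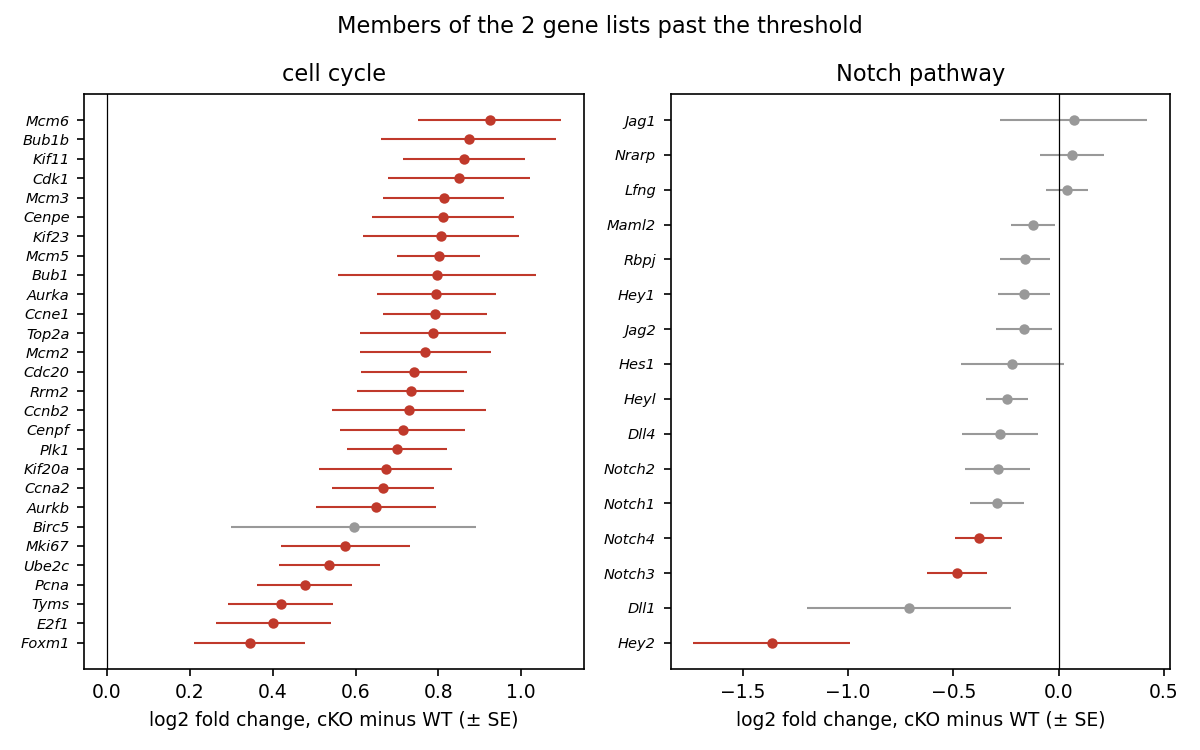
Log2 fold change (cKO minus WT) of each measured member of the cell cycle list (left) and of the Notch pathway list (right), as points with bars of 1 SE from limma (n = 4 per group). Red points passed when adjusted over the list alone, 27 of 28 and 3 of 16, and grey points did not; all cell cycle members lie above 0, and 13 Notch members lie below it.

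The lists of extracellular matrix, the substrate of the targeted protease, did not pass. Basement membrane genes had a mean difference of −0.39 with 16 of 19 lower (fry adjusted p 0.364, exact permutation p 0.0286), and 7 fell when adjusted over the list alone. Among these were the laminin chains Lama2 (−0.98, SE 0.22) and Lama3 (−0.80, SE 0.20), the proteoglycan Hspg2 (−0.65) and the collagen chain Col4a6 (−0.71). The list of fibrillar collagens and their processing enzymes also holds non-fibrillar chains, namely Col6a1, Col6a2, Col6a3, Col12a1 and Col14a1. It had a mean difference of −0.65 with 20 of 24 lower (fry adjusted p 0.390, exact permutation p 0.0286), and 8 fell when adjusted over the list alone. For this list and the basement membrane list, the permutation p equalled that of the lists that passed and was not adjusted over lists. The collagen VI chains Col6a1, Col6a2 and Col6a3 stood at −1.31 (SE 0.26), −1.29 (SE 0.28) and −0.81 (SE 0.22), and Col1a1 at −1.36 (SE 0.38). The collagen list score spread more among cKO tumors (−0.32 ± 0.53) than among WT tumors (0.32 ± 0.13, SD, n = 4 per group), with cKO 3 at −1.09, and without that tumor the mean difference was −0.39. Proteoglycans and matricellular proteins had a mean difference of −0.47 (adjusted p 0.421), and collagen uptake and lysosomal proteases −0.23 (adjusted p 0.466). Without cKO 3 these were −0.20 and −0.10. The matrix metalloproteinases other than Mmp14 had a mean of 0.06 with 10 of 17 higher (adjusted p 0.761). Within them the collagenase Mmp13 was higher by 1.52 (SE 0.47) and the gelatinase Mmp2, which the Mmp14 protein activates, stood at −1.24 (SE 0.43) and at −0.82 without cKO 3, neither past the threshold over all genes or over the list alone. Mmp10 differed by 0.42, and by 0.22 without cKO 2, and Mmp16 by −0.23. Other extracellular proteases and inhibitors had a mean of −0.20 (adjusted p 0.421), and of −0.08 without cKO 3.

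Markers of the cell types in the tumors were compared in the same way, and no cell type list passed. All 16 fibroblast markers were lower in cKO, by a mean of −0.60 (fry adjusted p 0.461), with none past the list's own threshold. Postn stood at −1.26, Col1a2 at −1.27 and Pdgfra at −0.71. The fibroblast score of the cKO tumors ran from −1.35 in cKO 3 to 0.56 in cKO 4, on either side of the WT tumors, which lay between 0.10 and 0.44. Without cKO 3 the mean difference was −0.25, with Postn at −0.78 and Col1a2 at −0.77. Macrophage markers had a mean of 0.21 and a median of 0.37 with 12 of 17 higher (adjusted p 0.364), and a mean of 0.14 without WT 4. Of these, 7 rose when adjusted over the list alone, among them Ms4a7 (1.01, SE 0.22), Adgre1 (0.68, SE 0.15), a surface receptor of macrophages, Aif1 (0.60, SE 0.14) and the complement gene C1qa (0.39, SE 0.12). Pericyte and smooth muscle markers had a mean of −0.33 (adjusted p 0.390), with Myh11 at −0.28, Abcc9 at −0.43 and Acta2 at −0.52. Endothelial markers had a mean of −0.24 (adjusted p 0.466). Without cKO 3 the means of these lists were −0.19 and −0.12, and Acta2 stood at −0.17. Abcc9 was at −0.28 without cKO 2. The endothelial transcription factor Erg (−0.59, SE 0.15) fell when adjusted over the list alone, while Kdr (−0.20), Vwf (−0.21) and Plvap (−0.28) did not pass. Without cKO 2 Kdr was at −0.11, and Plvap was at −0.43 without cKO 1 and −0.17 without cKO 3.

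Luminal epithelial markers had a mean difference of −0.23 and basal and myoepithelial markers one of −0.18, both with an adjusted p of 0.466. The first was −0.13 without WT 4 and the second −0.02 without cKO 3. Among the other immune lists, the mean was −0.08 for natural killer and cytotoxic cells (adjusted p 0.421), 0.05 for B cells (0.485), −0.14 for plasma cells (0.421) and 0.08 for T cells (0.761). It was −0.06 for neutrophils (0.755), 0.04 for dendritic cells (0.761) and 0.05 for mast cells (0.761). In the mast cell list Mrgprb1, at a mean of 2.48 in WT and 2.06 in cKO, fell when adjusted over the list alone. The natural killer list passed only in the mixed fry test, which asks for change in either direction (adjusted p 0.01), and had 4 members higher and 7 lower. For tissue around the tumors, the mean was −0.30 for skeletal muscle (0.755), −0.13 for skin keratinocytes (0.764) and −0.20 for nerve and Schwann cells (0.466). The muscle value rested on WT 2, with a score of 1.02. It was −0.0056 without that tumor and ran to −0.49 without WT 1 or WT 3, and the nerve value was −0.03 without cKO 3. Adipocyte markers had a mean of −0.05 with a median of 0.0027 (0.835), and lymphatic endothelial markers a mean of 0.01 with a median of −0.09 (0.868). In both of these the test pointed down, so that the signs of mean, median and test were not all alike.

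Lists of secretory and signalling genes did not pass either. Milk protein and secretory differentiation genes had a mean of −0.68 with 16 of 17 lower (adjusted p 0.364). The caseins varied within the groups, as in Csn1s2a with 7.96 ± 1.22 in WT and 5.56 ± 1.77 in cKO (SD, n = 4 per group), and Lao1 stood at −1.46, Muc1 at −0.69 and Xdh at −0.50. All 23 interferon response genes were lower, by a mean of −0.84, with none past the list's own threshold (adjusted p 0.421). Their score was 0.42 ± 0.71 in WT and −0.42 ± 0.56 in cKO (SD, n = 4 per group, exact permutation p = 0.114). Iigp1 stood at −1.49, Oas2 at −1.77, Mx1 at −0.91 and Ifit2 at −0.63. The mean was −0.18 for antigen presentation (0.466), 0.01 for inflammatory cytokines and chemokines (0.761) and −0.18 for growth factor receptors and ligands (0.364). It was −0.42 for immediate early genes (0.421), −0.19 for angiogenic factors (0.421) and −0.05 for TGF-beta targets (0.421). The TGF-beta list mixes targets with ligands, receptors and latent-binding proteins, with Tgfb1 at −0.49 and Tgfb2 at 0.58. Its mean is therefore not a measure of targets alone. The Wnt target list, which also holds the ligands Wnt4, Wnt5a, Wnt6 and Wnt10a, had a mean of 0.08 and a median of −0.0069. The test pointed down (0.882). Genes of the epithelial-mesenchymal transition had a mean of −0.25 (0.460), those of epithelial adhesion −0.07 (0.755), and those of invadopodia and cell motility −0.13 (0.492). Hormone receptor and hormone-sensing genes had a mean of −0.03 (0.918), hypoxia and glycolysis −0.14 (0.764), fatty acid and cholesterol synthesis 0.01 (0.755), the unfolded protein response −0.11 (0.755), ribosomal proteins 0.04 (0.761) and oxidative phosphorylation 0.07 (0.390). The values in parentheses are fry's adjusted p.

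**Figure D3:**
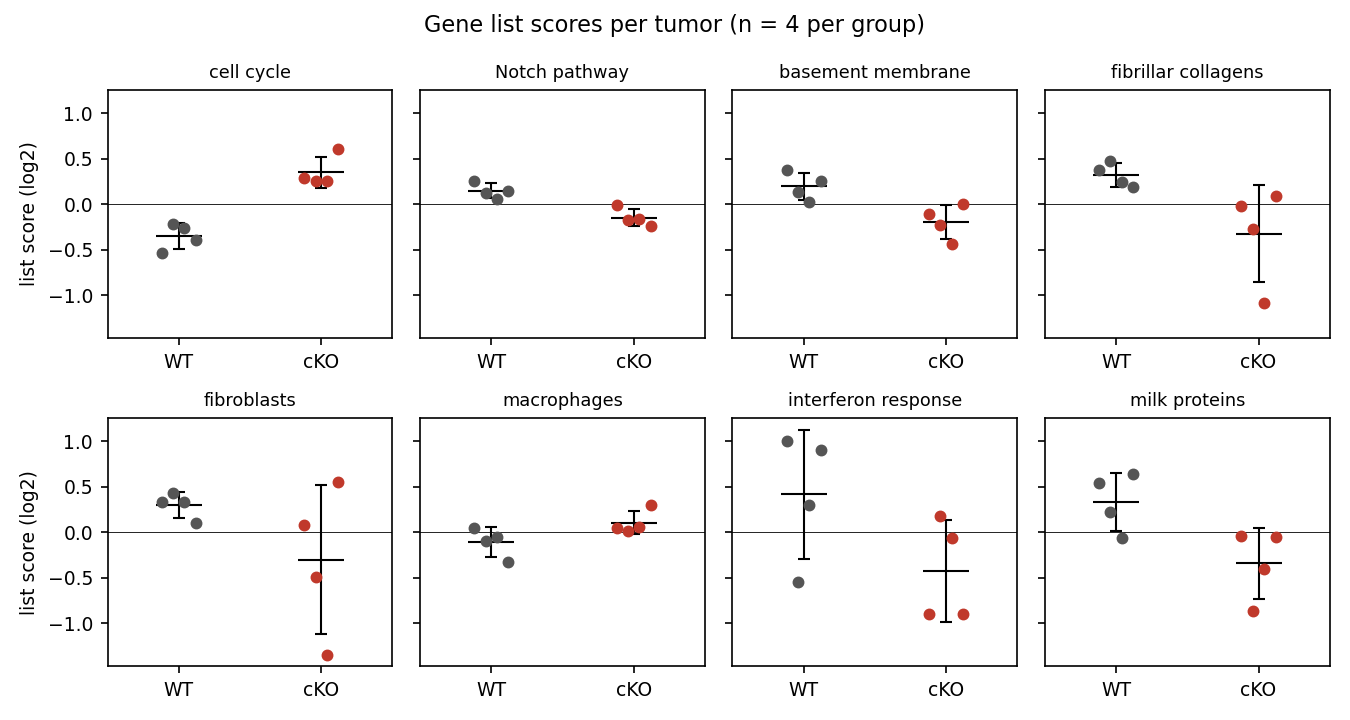
Scores of 8 gene lists in each tumor, as the mean over members of log2 signal minus the member's mean over all 8 tumors, with WT in grey, cKO in red, the mean as a line and the SD as error bars (n = 4 per group). The scores of the cell cycle, Notch pathway, basement membrane and fibrillar collagen lists do not overlap between the groups, but only the first 2 lists passed the threshold, and the fibroblast scores of cKO tumors run from −1.35 to 0.56.

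Without multiple-test adjustment, 6 lists had a fry p below 0.05. Camera with the preset correlation passed 22 lists, 2 higher and 20 lower, and with an estimated correlation it passed none, with 5 at an unadjusted p below 0.05. Leaving out some single tumor moved the mean of 37 of the 44 lists by over 1.5 times or changed its sign, most often cKO 3, with 25 lists. The 7 lists without such a move were cell cycle, Notch pathway, basement membrane, interferon response, milk proteins, growth factor receptors and oxidative phosphorylation.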

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

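The tests of skin, of fibroblast content, of the epithelial and macrophage shares and of the splits without Mmp14 were chosen only after the results they bear on had been seen. Of 120 sets of 4 values checked for a tumor far from the other 3 of its group, 32 of named genes and 88 of list scores, 12 stood out, where chance gives about 1 in 20. The number given for each is the gap to the nearest tumor as a share of the group's range.

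The agouti gene a was higher in every cKO tumor, by 3.04 on the log2 scale, and skin in the cKO samples is argued against by the skin keratinocyte markers, which differed by −0.135 (SE 0.199), with Krt10 at 3.72 in WT and 3.79 in cKO and Krt1 at 3.38 in both. That sign rested on WT 1, and without it the markers differed by 0.0617, still far below the agouti difference. A chromosome segment or transgene insertion that moves a whole neighbourhood cannot be told apart from a change of this gene alone. The median absolute t of the 20 nearest measured genes, 1.19, lay at percentile 89.02 of 10000 random windows, which meets neither bound set before the test. The largest absolute log2 difference among these neighbours was 0.40, that of E2f1, which is also on the cell cycle list. The Cre transgene and the loss of Mmp14, which the design joins, both stay open and were not tested apart.

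The cell cycle list was higher in cKO, and its score in cKO 4 (0.61) lay far above the other cKO tumors, between 0.25 and 0.28 (0.9165). Fewer fibroblasts in the cKO tumors are argued against as the whole cause, since with the fibroblast score as a covariate the difference was 0.799 (SE 0.113) against 0.701 (SE 0.111) without, with a fry adjusted p of 0.0347. A larger share of tumor epithelium is argued against by the luminal markers, at −0.234 (SE 0.177) and at −0.13 without WT 4. This holds only as far as these markers track that share, since Elf5 among them is also on the milk protein list, which had a mean of −0.68. Without cKO 4 the difference was 0.62, with an adjusted p of 0.0312. A larger share of macrophages cannot be told apart, since their markers had a mean of 0.212 (SE 0.103) and a median of 0.37 but went both ways, with 7 past their list's own threshold and Ms4a7 at 1.01, and the genotype stays open and untested.

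Mmp14 was lower in every cKO tumor. Fewer fibroblasts, which also express the gene, are argued against as the whole cause: with the fibroblast score as a covariate the log2 difference was −1.2852 (SE 0.146) against −1.40 (SE 0.13) without it. The adjusted p with the covariate was 0.0807, so that the call ended, with a larger SE and 1 degree of freedom fewer, while the difference moved by less than its SE. The deletion the labels name and a difference in cells outside the fibroblast list stay open.

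Among the 35 splits of the 8 tumors into 4 and 4, only the real 1 gave 2 genes past the threshold, and the highest of the others gave 1. For gene lists, too, only the real 1 of 35 gave 2 lists, and the highest other gave 1. The real split thus ranked first of 35, the best rank these splits allow, in both counts under the main settings. The count of genes held Mmp14, the targeted gene. The count of lists rested on the Notch list, whose fry adjusted p after the 2 rescalings of the arrays was 0.0803 and 0.122. A chance division of the tumors is therefore not excluded by these counts. For the genes other than Mmp14, 2 of the 35 splits gave 1 such gene, the real split (the agouti gene) and that of WT 1, WT 3, WT 4 and cKO 2 against the others. With the row of Mmp14 left out of the adjustment, the real split gave 0 genes and that other split still 1. The split by array number gave 0 genes and 0 lists.

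Outside the rows with 1 gene symbol, 6 unnamed rows passed when all 41345 rows were tested with limma, and all 6 were higher in every cKO tumor, by 2.27 to 3.67 on the log2 scale. They held 5 distinct sets of values, with the lowest cKO value at 7.01 and the highest WT value at 6.0. Among them were row 17551169, with a difference of 3.67, and row 17551165, with 3.53, both with an adjusted p of 0.0266. In all 6 rows cKO 1 was highest and cKO 2 lowest among the cKO tumors.

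Scnn1a was far lower in WT 2 (6.94) than in the other WT tumors, between 8.32 and 8.56 (0.8508). Ttc7 was lower in cKO 4 (6.08) than in the other cKO tumors, between 6.39 and 6.41 (0.9346). The macrophage score of cKO 4 (0.30) lay above the other cKO tumors, between 0.02 and 0.06 (0.8462), and so did its mast cell score of 0.25, with the others between −0.06 and −0.03 (0.9024). In cKO 2 the hypoxia and glycolysis score was 0.45, with the other cKO tumors between −0.32 and −0.20 (0.8514), and the inflammatory cytokine score 0.12, with the others between −0.04 and −0.03 (0.9554). In WT 1 the collagen uptake score was 0.24 against 0.07 to 0.08 in the other WT tumors (0.9297), and the skin keratinocyte score 0.66 against −0.17 to −0.06 (0.8773). The fatty acid and cholesterol synthesis score of WT 2 was −0.11, with the other WT tumors between 0.02 and 0.04 (0.8459). The basal and myoepithelial score of WT 3 was −0.21, with the others between 0.18 and 0.21 (0.9139). The natural killer score of WT 4 was −0.09, with the others between 0.08 and 0.10 (0.889).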

How the results depend on the processing

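The fibroblast covariate and the adjustments over brighter rows alone and without the row of Mmp14 were chosen after seeing the data. No named gene changed sign under any alternative. The differences of the agouti gene (2.77 to 3.30), of the cell cycle list (0.62 to 0.75) and of the Notch list (−0.34 to −0.26) kept their signs with 1 tumor left out, while their adjusted p passed the threshold in 2, 2 and 1 of the 8 fits. The gene count of 2 became 0 with the replicate block, 1 with the array number as a block (the agouti gene), 8 over all rows, 7 at an adjusted p of 0.10, 0 with the unmoderated two-sample test, 5 when adjusted over rows of mean at least 5 in the same fit, 0 when adjusted without the row of Mmp14 (agouti gene at 0.0889), and 0 with the fibroblast covariate. At an unadjusted p below 0.05 these fits of 0 genes held 1898, 2027, 2276 and 2340 rows. With 1 tumor left out the count ran from 0 to 3. Mmp14 stayed at −1.40 with the replicate block (adjusted p 0.353), the array number as a block (0.0708) and the unmoderated test (0.318), was −1.29 with the fibroblast covariate (0.0807), and ran from −1.48 to −1.30 with 1 tumor left out (0.0429 to 0.211). Over the other alternatives its adjusted p lay between 0.0192 and 0.0464. Blocks and left-out tumors cost residual degrees of freedom; otherwise the cause was not tested. The labels do not say whether a replicate number marks a litter or a day. The deviations of same-numbered tumors from their group means correlated at 0.01, −0.14, 0.24 and −0.18. Among the WT tumors, 1 of 4 correlated best with its own number. These few values cannot show whether the numbers pair the tumors. The list count of 2 became 1, the cell cycle list, after quantile normalization, the median shift, the filter on dim rows, array weights and the fibroblast covariate. In these settings the mean of the Notch list was −0.28, −0.28, −0.32, −0.29 and −0.30, so its call was lost with little change of the difference. The list count was 0 with the replicate block and with the array number as a block, 22 with camera's preset correlation, 0 with the estimated one (5 at an unadjusted p below 0.05), and 0 to 2 with 1 tumor left out. Lists that did not pass changed sign in 24 cases. These were inflammatory cytokines (−0.128) with the dim filter and adipocytes (0.0111) with array weights, and with the fibroblast covariate fatty acid synthesis (−0.0245), hormone-sensing genes (0.0233), endothelium (0.00065), adipocytes (0.109) and B cells (−0.00683). With 1 tumor left out the ranges were −0.212 to 0.0617 for skin keratinocytes, −0.0334 to 0.0664 for fatty acid synthesis, −0.0822 to 0.0324 for hormone-sensing genes, −0.162 to 0.124 for lymphatic endothelium, −0.0529 to 0.0507 for inflammatory cytokines, −0.122 to 0.0177 for epithelial adhesion, −0.319 to 0.00909 for hypoxia, −0.0182 to 0.0666 for dendritic cells, −0.14 to 0.0698 for adipocytes and −0.028 to 0.0847 for mast cells. Named genes other than Mmp14 kept sign and side of the threshold in 1148 cases, lost the call in 10, all of the agouti gene, and gained it in 6, while Mmp14 lost it in 10. Lists kept both in 753 cases, lost the call in 24 and gained it in 21. The median difference of all rows was 0.02 as deposited and 0.03 and 0.04 after the 2 rescalings. Signal over background was not used here, so what it limits for dim rows is unknown.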

Other observations

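The gene groups below, and the test of replication factors, were chosen after the gene values had been seen. All 37 measured DNA replication factors, which load, open and copy the DNA template, were higher in the cKO mean, by a mean of 0.52 on the log2 scale, and 33 passed when adjusted over this list alone. Mcm6 was higher by 0.92, Mcm5 by 0.80, Mcm4 by 0.74 and the chromatin assembly gene Chaf1b by 0.71. Scores ran from 0.14 to 0.45 in cKO tumors and from −0.39 to −0.11 in WT tumors (exact permutation p = 0.0286). Because 5 of the factors also stood on the cell cycle list and several had prompted the test, the 27 factors outside that list and outside the 50 smallest p-values were tested alone. All 27 were higher, by a mean of 0.449, with a fry p of 0.00144 and a camera p of 0.0137 with an estimated correlation. These factors belong to the same process as the cell cycle genes and were measured in the same tumors, so this is no independent evidence, and that replication factors are higher as a group in such tumors stays a hypothesis.

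The oligoadenylate synthetases and interferon-induced GTPases, antiviral effectors, were all lower in the cKO mean, 15 of 15, by a mean of −0.99, without passing (fry p 0.104, exact permutation p = 0.114). Oas2, Oas3, Oasl2, Mx1, Mx2, Iigp1, Igtp, Gbp3 and Gbp6 also stood on the interferon response list above. The values of this group are therefore no separate evidence. The group did not separate the genotypes. WT 2 stood at −0.56 while the other WT tumors lay between 0.38 and 1.12, and cKO 2 and cKO 3 stood at 0.12 and −0.11 while cKO 1 and cKO 4 stood at −1.0 and −0.98.

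Collagen VI and its receptors and partners had 6 of 9 members lower, by a mean of −0.47 (fry p 0.0646, and 0.0925 by camera with an estimated correlation). Scores ran from −0.68 in cKO 3 to 0.12 in cKO 4 among cKO tumors and from 0.18 to 0.31 in WT tumors (exact permutation p = 0.0286), and the mean difference was −0.33 without cKO 3. Beside this group the fibroblast markers had a mean difference of −0.60, and their score, too, was lowest in cKO 3 (−1.35) and highest in cKO 4 (0.56) among the cKO tumors. The 3 chains Col6a1, Col6a2 and Col6a3, whose values had been seen when the group was chosen, stood at −1.31, −1.29 and −0.81 and passed when adjusted over this list alone. The scores and tests of the group include these 3 chains and were not repeated without them. Their p-values are therefore no support beyond the chains that prompted the choice. The other chains among the 9 members, Col6a5 (−0.07) and Col6a6 (0.13), had mean signals below 4 in both groups. Matn2 stood at −0.68, Antxr1 at −0.43, Cspg4 at 0.05 and the receptor Antxr2 at 0.14.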
